A study of Mus musculus with 3 samples.

How the data were processed

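Per the labels, tumours were digested with 0.25% trypsin and DNase I at 37 degrees for about 40 minutes and freed of red cells, and droplets then captured polyadenylated RNA, tagged at the transcript's 3' end with cell barcode and UMI. The authors deposited, for each of the 3 libraries, a matrix of UMI counts for 32285 genes and the barcodes called as cells, and per the file headers these were made with Cell Ranger 5.0.1. The submitters' processing notes also name STAR, Seurat 4.1.1 and the mouse build mm10; the annotation release is not given in the sources used here. The deposited counts are whole numbers without normalization. No file with cell types was used, so the names of cells below were rebuilt and can differ from the study's own.

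Cells with at least 200 genes and a mitochondrial share under 20% were kept, which left out 269, 240 and 396 barcodes with fewer genes in the vehicle, MCB-294 and MCB-36 libraries and 192, 228 and 203 with a higher mitochondrial share. Doublets were scored with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold marked 0 cells with vehicle and with MCB-294 and 359 with MCB-36, so a common score limit of 0.2 was set after seeing the scores; it removed 448, 379 and 428 cells. The cells kept were 91.8%, 91.8% and 90.4% of the barcodes, 29399 in all. Counts were scaled to 10000 per cell and logged, and 2000 variable genes without mitochondrial and ribosomal protein genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, seed 1) gave the clusters. The libraries were clustered together without batch correction.

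Clusters were named from 26 marker sets fixed before the data were examined, and so were the gene lists, the comparisons, the named-gene rule and most of the alternative settings. The scoring rule was set after the clusters were seen: a marker's level is its CPM divided by its highest CPM in any cluster, and the class with the highest mean level and at least 3 detected markers (10 CPM and 20% of the highest cluster) names the cluster. A cluster stayed unnamed when another class with at least 3 detected markers reached over 50% of that score, except between monocytes and macrophages, when its top 10 genes held more markers of another class, or when it was shallow with no own marker among them. Unnamed clusters included one of 142, 174 and 219 shallow cells with macrophage-like genes. T- and NK-like cells were clustered again to name sub-classes.

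For each class with at least 50 cells in every library, counts were summed per library and expressed as CPM. A level carries an exact Poisson interval and a ratio of levels an exact conditional one; shares of cells carry exact Clopper-Pearson intervals. All are at 95% and cover counting error only, which is wider at the 413253 to 876935 UMIs of T- and NK-like cells than at the 91172083 to 106308017 UMIs of tumour-like cells. With 1 library per group there is no test, no p-value and no leave-one-out check. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs, or to 1000 for Cd8a, Cd4 and Foxp3.

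Of 41 gene lists, those with at least 3 measured members in a class (10 CPM and 20 counts in at least 1 library) were summarised by the median of log2((CPM + 1)/(CPM + 1)), its percentile among 10000 random lists of the same size matched on mean expression, a bootstrap interval over members from 2000 draws, and the number of members at least 1.5-fold higher or lower; 36 lists were measured in at least 1 class. Percentiles and bootstrap intervals describe these libraries, not the conditions. MHC class II genes in T-, NK- and fibroblast-like cells lay over 10 times higher in another class and are not reported. Of the listed symbols, Mx1, Cxcl11, Cyr61, Ctgf, Trgc1 and Trgc2 have no row in the files, and 38 symbols shared by more than 1 gene ID were read from the ID with the most UMIs.

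The text names genes by this rule, per compound against vehicle: in tumour-like cells the 10 largest and 10 smallest values of log2((CPM + 5)/(CPM + 5)) among genes with at least 25 CPM and 50 counts in the higher library; in the 4 host classes with the most cells the 3 largest and 3 smallest; up to 4 members with the largest absolute log2 ratio from each list described; and Kras, Hras and Nras. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor, predicted and sex-linked marker genes were left out of the top lists, and so were genes over 10 times higher in another class of the library. Genes outside the rule are named as such.

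RNA of tumour-like cells inside each host class was estimated from 50 tumour genes of at least 100 CPM that are lowest in the other immune classes, or for fibroblast-like cells lowest in that class. Coordinates are those of GENCODE vM21 on GRCm38, matched by gene ID; all genes given with coordinates are annotated as protein-coding, and the interval is that of the whole gene.

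The calculation was tested on simulated data with 200 genes of known ratio. The counts were drawn with Poisson error only, from 1 profile shared by all libraries, without variation between cells, animals or libraries. The test therefore checks the arithmetic and the counting error, and cannot show how often differences between libraries give false calls. For MCB-294 against vehicle in tumour-like cells (6806 genes), 100% of genes simulated at 2-fold, 26.8% of those at 1.5-fold and 0% of 6606 unchanged genes were called, and 95.3% of intervals of unchanged genes held the true ratio. In T-like cells (4289 genes) the shares were 93.4%, 40.3% and 13.8% of 4089 unchanged genes, so single T-like calls near 1.5-fold are unsafe.

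Alternatives were edgeR 4.0.16 TMM scaling, DESeq2 1.42.0 size factors, CPM without mitochondrial and ribosomal protein genes, the mean over cells of each cell's CPM, a stricter cell filter (500 genes, mitochondrial share under 10%), no mitochondrial limit, doublets kept, thinning, clustering at resolution 0.5 and 2, each library clustered on its own, a stricter minimum for measured genes (50 CPM and 100 counts), a 2-fold limit, and a constant of 1 CPM for the named genes. Chosen after seeing the data were CPM without Gm42418 and AY036118, lists without members over 10 times higher in another class, tumour-like cells without a G2/M UMI, tumour RNA taken off the host classes, and the unthinned shares. Cells without a G2/M UMI were found, and their medians taken, after thinning each cell to 2000 UMIs. In the thinning alternative list members were measured anew, among 1927 in place of 4300 genes in NK-like cells. In fibroblast-like cells there were 2163 in place of 6807 genes. Medians after thinning can therefore rest on fewer members. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used.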

Results

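The transcriptomes of single cells were counted in 3 libraries of CT26 tumours, 1 library per group, made by droplet capture with unique molecular identifiers (UMIs). CT26 is a mouse colon carcinoma line with an activating Kras mutation. It derives from BALB/c mice, while the labels record tumours grown in male C57BL/6 mice, a strain label that the values leave in doubt. The mice received vehicle, MCB-294 at 30 mg/kg or MCB-36 at 60 mg/kg for 2 days, by the labels bid, that is 2 times a day. By the series title MCB-294 is a pan-KRAS inhibitor and MCB-36 a degrader derived from it, and the design text asks how each acts on the tumour microenvironment. The deposited matrices held 11080 barcodes and 120371879 UMIs for vehicle, 10370 barcodes and 107957137 UMIs for MCB-294, and 10732 barcodes and 129349341 UMIs for MCB-36. After filtering, 10171, 9523 and 9705 cells were kept in the same order, with a median of 9293, 8925 and 10493 UMIs per cell.

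With 1 library per group, no difference has a replicate check and no test was made. Intervals beside CPM ratios and shares of cells cover counting error only, at 95%. "Higher" and "lower" are used of a list member when its level, with 1 CPM added to each side, differs by at least 1.5-fold, and of other values when their intervals exclude a ratio of 1. Both compounds are compared with the same vehicle library, so a peculiarity of that library enters both comparisons. The compounds were also given at different doses. Levels are in CPM, UMI counts summed over the cells of a class and scaled to a common total, and in the form 7.74 against 45.2 CPM the compound's library comes first.

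The first question was which cells the tumours held. CT26 tumour-like cells made up 74.2% of kept cells with vehicle (73.3 to 75.04), 76.2% with MCB-294 (75.3 to 77.1) and 68.6% with MCB-36 (67.7 to 69.5). Macrophage-like cells, the most abundant host class, were 12.7% (12.1 to 13.4), 9.98% (9.38 to 10.6) and 13.5% (12.8 to 14.2). Monocyte-like cells were 2.22% with vehicle (1.94 to 2.53), 3.95% with MCB-294 (3.57 to 4.36) and 3.30% with MCB-36 (2.95 to 3.67), a ratio to vehicle of 1.78 (1.503 to 2.11) and 1.48 (1.25 to 1.77). T-like cells were 2.497% (2.20 to 2.82), 2.25% (1.96 to 2.57) and 3.82% (3.45 to 4.22), so that the MCB-36 library held 1.53 times the vehicle share (1.30 to 1.80). NK-like cells were 2.79% (2.48 to 3.13), 2.80% (2.48 to 3.16) and 3.48% (3.13 to 3.87). These T- and NK-like shares are out of all kept cells, so the smaller tumour-like share with MCB-36 by itself raises them. Dendritic-like cells numbered 43, 11 and 42, a ratio to vehicle of 0.273 with MCB-294 (0.127 to 0.539) and 1.02 with MCB-36 (0.653 to 1.60). Fibroblast-like cells were 1.30% (1.09 to 1.54), 1.01% (0.817 to 1.23) and 1.41% (1.19 to 1.67). Endothelial-like cells numbered 30, 30 and 32, mast- or basophil-like cells 27, 20 and 42, and neutrophil-like cells 10, 23 and 20. Unnamed clusters held 3.19%, 2.94% and 4.49% of cells. The shares carry the tissue dissociation with them, and counting the same cells out of all cells not named tumour-like, unnamed ones included, gave a monocyte-like share of 8.61%, 16.6% and 10.5% and a macrophage-like share of 49.3%, 41.9% and 43.0%. Under the stricter cell filter, without a mitochondrial limit and at the lower clustering resolution, the monocyte-like cluster was not separate from the macrophage-like ones, and together they made up 14.95%, 13.9% and 16.8% of cells in the main clustering. With each library clustered on its own, no monocyte-like cluster was named for vehicle or MCB-36. The ratio to vehicle of both classes together with MCB-294 was then 1.22 in place of 0.931.

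**Figure D1:**
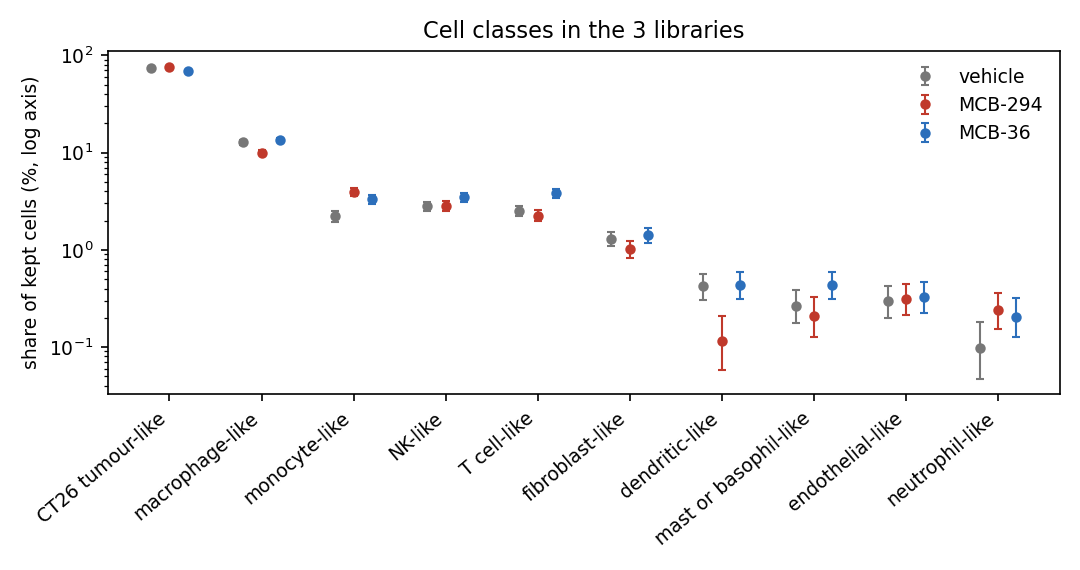
Share of kept cells (percent, log axis) in the tumour-like class and each named host class for the vehicle, MCB-294 and MCB-36 libraries. Exact 95% binomial intervals cover counting error only. The monocyte-like share is 2.22%, 3.95% and 3.30%, and the T-like share 2.497%, 2.25% and 3.82%.

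Among the 538, 481 and 709 T- and NK-like cells, regulatory T-like cells, which carry the lineage factor Foxp3, were 9.67% with vehicle (7.30 to 12.5), 6.86% with MCB-294 (4.77 to 9.50) and 10.7% with MCB-36 (8.54 to 13.2). Their ratio to vehicle was 0.710 (0.445 to 1.12) with MCB-294 and 1.11 (0.769 to 1.61) with MCB-36. Between the compounds the MCB-36 library held 1.56 times the MCB-294 share (1.03 to 2.43). That interval included 1 under 4 of 6 alternative settings. CD8 T-like cells, the cytotoxic lineage, were 28.8% (25.0 to 32.8), 24.5% (20.8 to 28.6) and 30.3% (27.0 to 33.9). That share depended on the clustering: at the lower resolution its ratio to vehicle was 0.224 with MCB-294 and 0.240 with MCB-36, and at the higher one 1.55 and 1.68. CD4 T-like cells other than regulatory ones were 6.69%, 9.56% and 8.89%. This share depended on the processing too: it was 0%, 4.93% and 1.14% with each library clustered on its own. Without a mitochondrial limit its ratios to vehicle were 1.85 (1.21 to 2.86) and 1.97 (1.33 to 2.95), and with doublets kept 1.28 and 1.22. Counted by single genes in T-like cells thinned to 1000 UMIs, Cd8a was seen in 13.99% of 193 cells with vehicle, 14.2% of 176 with MCB-294 and 16.3% of 320 with MCB-36, against 26.4%, 20.6% and 22.4% of all T-like cells before thinning. Cd4 was seen in 4.66%, 10.8% and 7.19% after thinning (9.06%, 16.8% and 14.8% before), and Foxp3 in 2.59%, 2.84% and 2.81% (5.12%, 6.08% and 5.39% before). In NK-like cells, which should lack all 3 genes, none was seen in 238, 219 and 299 cells. Thinning left out 61, 38 and 51 shallower T-like cells, and median depth before it was 1589, 1523 and 1606 UMIs.

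Fewer tumour-like cells carried transcripts of dividing cells with either compound. Top2a (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189, minus strand of GRCm38), which codes the topoisomerase that untangles replicated chromosomes, was seen after thinning each cell to 2000 UMIs in 16.2% of cells with vehicle (15.4 to 17.1), 9.40% with MCB-294 (8.73 to 10.1) and 11.9% with MCB-36 (11.2 to 12.7). Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361, minus strand), the proliferation antigen, was seen in 5.77% (5.25 to 6.32), 3.38% (2.97 to 3.82) and 4.13% (3.67 to 4.64). Before thinning the shares were 40.6%, 25.8% and 33.7% for Top2a and 28.1%, 15.2% and 21.7% for Mki67. Thinning used 7488, 7161 and 6628 cells and left out 58, 95 and 29. Summed Mki67 was 49.2 CPM with vehicle, 33.2 with MCB-294 and 32.8 with MCB-36, so no order between the compounds is read for Mki67. Median depth before thinning was 12009, 10865 and 14318 UMIs. Too few neutrophil-like cells reached 2000 UMIs (1, 9 and 5) to give a background.

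The main comparison asked what the inhibitor MCB-294 did to the tumour cells. MAPK output genes, which ERK signalling switches on downstream of KRAS, were lower with MCB-294 than with vehicle in tumour-like cells: 7 of 12 measured members were lower and none higher, with a median log2 ratio of -1.03 (-1.60 to -0.48), where brackets give a bootstrap interval over members, below all 10000 random lists matched on expression. Genes of mitosis, cholesterol synthesis and immediate early genes were lower beside them. The medians of interferon response genes and of antigen presentation genes of MHC class I lay above those of all random lists, with 6 of 19 and 2 of 13 members higher. Of the 10 tumour-like clusters, the vehicle cells lay mostly in clusters 1, 6 and 0 and the MCB-294 cells mostly in clusters 2, 0 and 3. Each of these clusters had part of the CT26 marker set detected, from 4 markers in cluster 1 to 9 in cluster 8. Cluster 2 had 5. Only cluster 5 held a CT26 marker among its top 10 genes.

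Among MAPK output genes, Dusp5 (ENSMUSG00000034765, chromosome 19, 53529109 to 53542431, plus strand), a nuclear ERK phosphatase, measured 7.74 against 45.2 CPM (ratio 0.171, 0.158 to 0.186). Phlda1 (ENSMUSG00000020205, chromosome 10, 111506286 to 111508645, plus strand) measured 184 against 649.7 CPM (0.284, 0.279 to 0.289). Fosl1 (ENSMUSG00000024912, chromosome 19, 5447547 to 5455946, plus strand), a FOS-family transcription factor, measured 40.2 against 138 CPM (0.291, 0.281 to 0.302), and Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925, minus strand), the cyclin that starts the cell cycle, 404 against 861 CPM (0.470, 0.464 to 0.475). The receptor Epha2 measured 14.4 against 41.0 CPM and the phosphatase Dusp4 5.25 against 12.8 CPM. Dusp6 (ENSMUSG00000019960, chromosome 10, 99263231 to 99267489, plus strand) and Spry4 (ENSMUSG00000024427, chromosome 18, 38586247 to 38601415, minus strand), feedback inhibitors of the pathway picked out after their values were seen, measured 48.2 CPM with vehicle, 34.6 with MCB-294 and 56.6 with MCB-36, and 22.4 CPM with vehicle, 15.7 with MCB-294 and 30.3 with MCB-36. The target gene Kras (ENSMUSG00000030265, chromosome 6, 145216699 to 145250239, minus strand) measured 107 against 129.9 CPM (ratio 0.827, 0.806 to 0.849), Hras 140.3 against 220.5 CPM (0.636, 0.623 to 0.650) and Nras 60.9 against 70.8 CPM (0.860, 0.831 to 0.891). Of 6 RAS genes 1 was lower, Hras, and the median was -0.24 (-0.54 to 0.13). Growth factor receptors upstream of RAS had a median of 0.12 (-0.37 to 0.49) over 5 members.

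Immediate early genes, the first genes induced by growth factors, were lower for 8 of 13 members (median -0.95 (-1.36 to -0.31)). Ier2 measured 229 against 670.5 CPM, Ier3 163 against 458 CPM and Egr3 8.53 against 25.4 CPM, while Dusp1, a stress-induced phosphatase, was the 1 member that was higher, at 629 against 295 CPM. In mitosis (G2/M) 19 of 22 genes were lower (median -0.91 (-1.11 to -0.77)), among them Cdc20 (63.4 against 156 CPM), Cenpa (91.2 against 217 CPM), Plk1 (10.5 against 26.0 CPM) and Ccna2 (34.5 against 82.2 CPM). DNA replication (G1/S) had 6 of 18 lower (median -0.48 (-0.59 to -0.34)), including the ribonucleotide reductase subunit Rrm2 (56.8 against 94.5 CPM) and Uhrf1 (25.3 against 42.0 CPM). Ribosome biogenesis had 6 of 14 lower (median -0.48 (-0.71 to -0.30)), with the polyamine enzymes Odc1 (186 against 389 CPM) and Srm (66.2 against 127 CPM).

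Metabolic lists followed. All 10 measured cholesterol synthesis genes were lower (median -1.06 (-1.41 to -0.93)): Msmo1 measured 40.6 against 139 CPM, Fdps 80.3 against 268 CPM, Idi1 26.4 against 64.6 CPM and Sqle 31.1 against 67.9 CPM. Glycolysis had 7 of 15 lower (median -0.56 (-0.70 to -0.32)), with the glucose transporter Slc2a1 at 21.0 against 36.1 CPM and the lactate exporter Slc16a3 at 5.28 against 12.2 CPM. Hypoxia-inducible genes had 3 of 9 lower (median -0.39 (-0.72 to -0.10)), such as Ero1l (44.8 against 87.1 CPM) and Hilpda (42.1 against 70.0 CPM). In the unfolded protein response 5 of 10 were lower (median -0.62 (-1.48 to -0.26)); these were led by Trib3 (2.92 against 15.8 CPM), Chac1 (4.96 against 23.8 CPM) and Asns (70.5 against 198 CPM), which the stress factor ATF4 induces. Lysosome and autophagy genes had 2 higher and 1 lower of 11 (median 0.18 (-0.11 to 0.46)), with Lamp2 at 127 against 77.1 CPM and the autophagy receptor Sqstm1 at 94.6 against 147 CPM. Of the genes that can kill a cell, the BH3-only gene Bbc3 (PUMA) measured 38.5 against 76.5 CPM, and the 4 measured BH3-only genes had a median of -0.42 (-0.97 to -0.19).

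Signals that tumour cells send to immune cells differed in both directions. Attractants of myeloid cells were lower for 6 of 8 members (median -0.81 (-1.53 to -0.50)): Csf2, the cytokine GM-CSF, measured 3.93 against 36.5 CPM (ratio 0.108, 0.0963 to 0.120), the neutrophil chemokine Cxcl1 798 against 1564 CPM, Lif 5.64 against 18.1 CPM and Ptgs2, which codes the prostaglandin enzyme COX-2, 89.2 against 174 CPM. Interferon response genes were higher for 6 of 19 (median 0.44 (0.24 to 0.65), above all random lists), with Gbp5 at 19.7 against 8.15 CPM, Ifi47 at 94.0 against 50.6 CPM, Igtp at 62.3 against 36.1 CPM and Stat1 at 75.1 against 46.9 CPM. MHC class I genes were higher for 2 of 13 (median 0.31 (0.12 to 0.54)), namely H2-T23 (49.0 against 21.2 CPM) and the peptide transporter Tap2 (95.6 against 55.0 CPM); B2m measured 1611 against 1110 CPM. At a 2-fold limit the higher interferon genes numbered 1 in place of 6 and the lower G2/M genes 9 in place of 19.

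Lcn2, lipocalin 2, was furthest above vehicle with 5 CPM added to each side. It falls outside the naming rule, being over 10 times higher in another class, and was picked out after its values were seen. It measured 10.4 CPM with vehicle, 96.7 with MCB-294 and 44.1 with MCB-36. Among the genes that the rule admits, those furthest above vehicle with MCB-294 were Rcan2, a calcineurin regulator (31.0 against 3.56 CPM, ratio 8.71, 7.80 to 9.75), and Edn1, the precursor of the vasoconstrictor endothelin (25.6 against 2.63 CPM, ratio 9.74, 8.58 to 11.1). F3, tissue factor, measured 95.7 against 24.0 CPM, Xdh, an enzyme of purine breakdown, 156 against 41.9 CPM, and the transcription factor Cebpd 493 against 143 CPM. Selenbp1 measured 35.1 against 7.16 CPM, Jcad 51.0 against 13.4 CPM, Spsb1 46.9 against 12.4 CPM, Txnip, which limits glucose uptake, 167 against 53.2 CPM, and Id1, an inhibitor of differentiation factors, 86.0 against 26.4 CPM. Furthest below vehicle were the natriuretic peptide gene Nppb (8.41 against 85.5 CPM, ratio 0.0984, 0.0913 to 0.106), Esm1 (28.5 against 163 CPM) and Csf2. The urokinase receptor Plaur measured 41.0 against 193 CPM, the EGF receptor ligands Hbegf 65.4 against 259 CPM and Areg 9.14 against 45.8 CPM, the cytokine Il11 6.07 against 36.03 CPM and the mitochondrial folate enzyme Mthfd2 66.4 against 224 CPM. Dusp5 and Phlda1 belonged to the same 10 genes.

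Further lists, with medians inside the central 95% of random lists with MCB-294, were heat shock (-0.28 (-0.51 to -0.01)), checkpoint ligands (-0.10 (-0.54 to 0.32)), p53 targets (-0.14 (-0.52 to 0.35)), mesenchymal genes (-0.22 (-0.79 to 0.28)) and YAP targets (0.15 (-0.47 to 0.79)). The RNA quality list had a median of 0.12 (-0.28 to 0.55). Of its members, Malat1 measured 1.46 times vehicle with MCB-294 and 0.945 with MCB-36, and 0.648 for MCB-36 to MCB-294. Neat1 measured 0.824 and 0.835 times vehicle. Tumour-like cells had a median mitochondrial share of 5.85% with vehicle, 6.91% with MCB-294 and 5.64% with MCB-36.

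**Figure D2:**
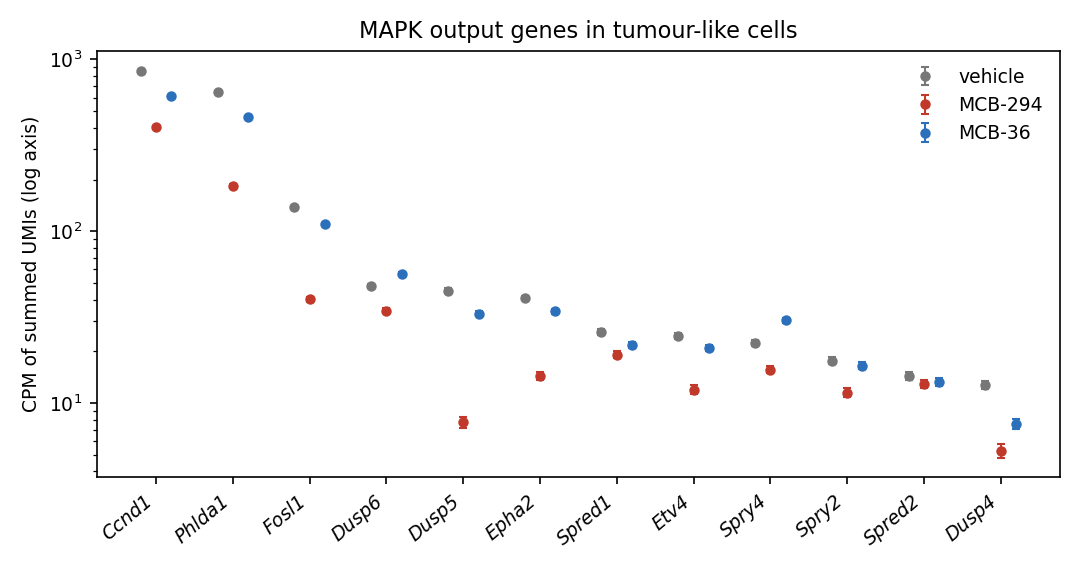
CPM of the measured MAPK output genes in tumour-like cells (log axis), 1 point per library, with exact 95% Poisson intervals that cover counting error only. Dusp5 lies at 45.2, 7.74 and 33.2 CPM with vehicle, MCB-294 and MCB-36.

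The next comparison set the degrader MCB-36 against vehicle in tumour-like cells. Most lists lay on the same side of vehicle as with MCB-294 but nearer to it. MAPK output genes had 1 of 12 lower and none higher, with a median of -0.25 (-0.46 to -0.10) at percentile 0.09 of random lists. Cholesterol synthesis was the list with the most lower members, 4 of 10, and Mt1, Mt2 and Tsc22d3 were among the 10 named genes furthest above vehicle. The largest clusters of this library were 0, 3 and 5.

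Dusp5 measured 33.2 against 45.2 CPM (ratio 0.734, 0.703 to 0.768), Phlda1 460.2 against 649.7 CPM (0.708, 0.700 to 0.717), Fosl1 109.6 against 138 CPM and Ccnd1 614 against 861 CPM; Dusp4 (7.57 against 12.8 CPM) was the member called lower. Kras had a ratio to vehicle of 0.770 (0.751 to 0.790), Hras 179 against 220.5 CPM and Nras 66.9 against 70.8 CPM, and the RAS list had a median of -0.14 (-0.34 to 0.00). These are RNA levels, and the protein that a degrader removes was not measured here. None of the 22 G2/M genes was called, yet their median was -0.42 (-0.46 to -0.35), below all random lists. Without any member called, G1/S genes had a median of -0.25 (-0.32 to -0.15), also below all random lists, and ribosome biogenesis genes -0.18 (-0.25 to -0.07). The median of immediate early genes was -0.18 (-0.26 to -0.04), that of the unfolded protein response -0.19 (-0.35 to 0.04) and that of myeloid attractants -0.40 (-0.47 to -0.19). Lower cholesterol genes included Idi1 (42.3 against 64.6 CPM), Sqle (44.7 against 67.9 CPM) and Hmgcs1 (59.7 against 92.0 CPM), and the list's median was -0.46 (-0.60 to -0.36). Interferon response genes had a median of 0.17 (0.02 to 0.25) and MHC class I genes of 0.20 (0.16 to 0.29), both above all random lists with no member called. In tumour-like cells without a G2/M UMI after thinning to 2000 UMIs the interferon median was -0.02, so that this direction was not kept.

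Of the genes that the rule admits, the 10 furthest above vehicle with MCB-36 included the metallothioneins Mt2 (1977 against 902 CPM, ratio 2.19, 2.18 to 2.21) and Mt1 (2727 against 1394 CPM), which bind metals, and Tsc22d3, the glucocorticoid-induced leucine zipper (171 against 81.9 CPM, ratio 2.08, 2.03 to 2.14). Arl4d measured 31.9 against 13.3 CPM, the matricellular Ccn2 73.9 against 35.1 CPM, glutamine synthetase (Glul) 70.2 against 36.7 CPM, transglutaminase (Tgm2) 53.9 against 28.6 CPM, Spsb1 27.4 against 12.4 CPM, Xdh 78.3 against 41.9 CPM and Cebpd 257 against 143 CPM. The 10 furthest below included the clock output genes Dbp (9.34 against 42.4 CPM, ratio 0.220, 0.205 to 0.236) and Nr1d1 (20.1 against 39.1 CPM) and the matrix proteoglycans Ogn (39.4 against 75.7 CPM) and Aspn (32.1 against 55.7 CPM). The linker histones Hist1h1b and Hist1h1e measured 99.0 against 169 CPM and 63.0 against 104 CPM, the chaperone Hsph1 73.3 against 116 CPM, connexin 43 (Gja1) 25.4 against 42.1 CPM, Apod 22.4 against 37.2 CPM and the sterol enzyme Cyp51 59.1 against 93.1 CPM.

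With MCB-36, glycolysis had a median of -0.03 (-0.18 to 0.05), hypoxia -0.16 (-0.31 to -0.01), heat shock -0.15 (-0.31 to -0.05), checkpoint ligands -0.01 (-0.23 to 0.11), p53 targets -0.14 (-0.24 to 0.09), BH3-only genes -0.20 (-0.53 to 0.17), mesenchymal genes -0.07 (-0.31 to 0.16), YAP targets -0.04 (-0.33 to 0.55) and growth factor receptors 0.01 (-0.61 to 0.39). Lysosome and autophagy genes had 0.17 (0.04 to 0.21) with none called, and the RNA quality list -0.24 (-0.26 to -0.08).

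Set directly side by side at their different doses, the MCB-36 library had the higher MAPK output in tumour-like cells: 8 of 12 members were higher than with MCB-294 and none lower (median 0.72 (0.47 to 1.25), above all random lists). Dusp5 measured 33.2 against 7.74 CPM (ratio of MCB-36 to MCB-294 4.28, 3.95 to 4.65), Fosl1 109.6 against 40.2 CPM (2.73, 2.63 to 2.83) and Phlda1 460.2 against 184 CPM (2.495, 2.45 to 2.54). Immediate early genes had 7 higher and 1 lower of 13 (median 0.74 (0.27 to 0.95)), G2/M 11 of 22 higher (median 0.56 (0.36 to 0.71)), cholesterol synthesis 6 of 10 (median 0.65 (0.46 to 1.02)) and glycolysis 5 of 15 (median 0.38 (0.24 to 0.61)). Myeloid attractants had 3 of 8 higher, with Csf2 at 24.4 against 3.93 CPM and Cxcl1 at 1348 against 798 CPM. Interferon response genes were on the lower side (median -0.30 (-0.39 to -0.25), 1 of 19 called lower). At a 2-fold limit the higher MAPK output genes numbered 4 in place of 8 and the higher G2/M genes 0 in place of 11.

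**Figure D3:**
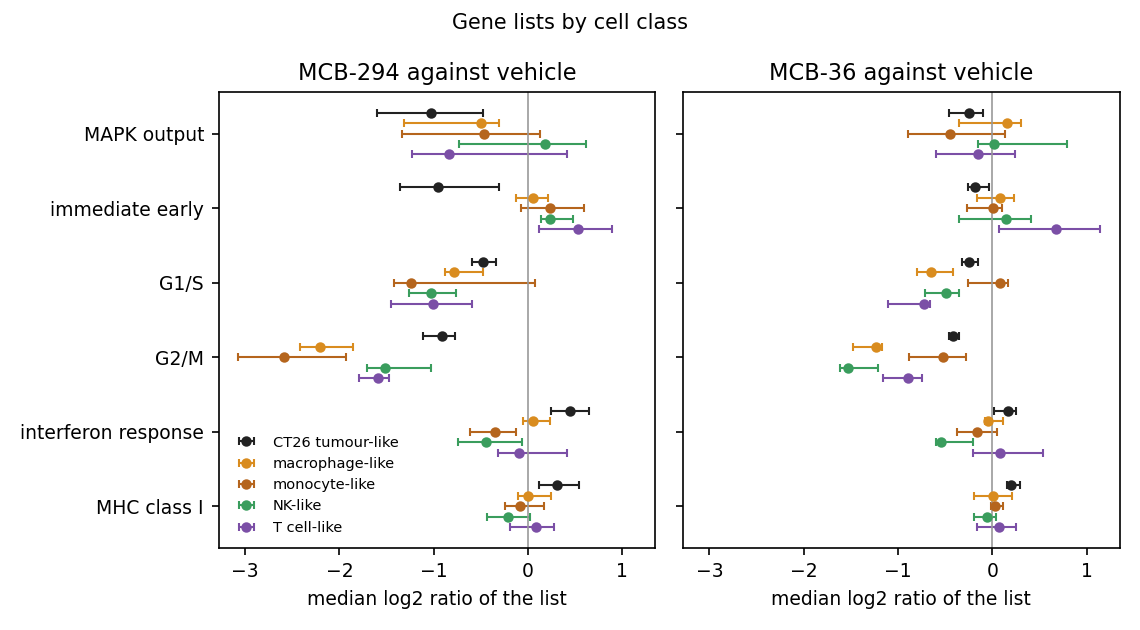
Median log2 ratio to vehicle of gene lists in each cell class, for MCB-294 and MCB-36, with bootstrap intervals over list members. In tumour-like cells the MAPK output list lies at -1.03 with MCB-294 and -0.25 with MCB-36.

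In the host classes, the question was how cells of the microenvironment differed between libraries. Mitosis genes were lower with both compounds in macrophage-like cells, with all 22 measured genes lower and a median of -2.21 (-2.42 to -1.86) with MCB-294 and -1.23 (-1.48 to -1.17) with MCB-36. NK-like cells had all 12 lower with each compound (median -1.52 (-1.71 to -1.03) and -1.53 (-1.62 to -1.21)). In T-like cells 17 of 17 were lower with MCB-294 (median -1.59 (-1.79 to -1.47)) and 15 with MCB-36 (median -0.89 (-1.16 to -0.75)), and in monocyte-like cells 12 of 12 with MCB-294 (median -2.59 (-3.07 to -1.93)) and 4 with MCB-36, where 1 was higher (median -0.52 (-0.88 to -0.28)). G1/S medians were -0.78 (-0.88 to -0.48) and -0.65 (-0.80 to -0.42) in macrophage-like, -1.03 (-1.26 to -0.76) and -0.49 (-0.71 to -0.35) in NK-like, -1.01 (-1.45 to -0.59) and -0.72 (-1.11 to -0.66) in T-like and -1.24 (-1.42 to 0.07) and 0.08 (-0.26 to 0.17) in monocyte-like cells. RNA of tumour-like cells was present in these classes at 4.26% to 10.1% of its level in tumour-like cells.

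Some T-like values depended on the doublet setting, under which a small cluster lost its name. That setting also kept the called doublets and clustered the cells anew, so the part of this cluster alone was not tested. Of the 254, 214 and 371 T-like cells, 71, 15 and 40 lay in a deeper cluster of CD8 T-like cells that was left unnamed when cells called doublets were kept. The G2/M median of T-like cells with MCB-36 was then -0.02, that of exhaustion genes 0.03, and the MCB-36 share of T-like cells 1.94 times that of vehicle.

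Macrophage-like cells with MCB-294 had less of the monocyte chemokine Ccl12 (ENSMUSG00000035352, chromosome 11, 82101845 to 82103400, plus strand), 149 against 1682 CPM (ratio 0.0885, 0.0814 to 0.0959), of Fcrls (7.82 against 71.7 CPM) and of the cyclin Ccnb2 (4.50 against 48.1 CPM). They had more of the acute-phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, minus strand), 303 against 43.1 CPM (ratio 7.03, 6.08 to 8.16), of Cbfa2t3 (32.0 against 3.22 CPM) and of Ms4a8a (55.2 against 10.7 CPM). MAPK output genes were lower for 3 of 8 members (median -0.50 (-1.31 to -0.31)), with Ccnd1 at 87.0 against 286 CPM and Etv5 at 10.9 against 28.6 CPM; T cell attractants were lower for 4 of 6 (median -0.73 (-1.06 to -0.02)), with Ccl3 at 358 against 746 CPM, Ccl4 at 1693 against 3513 CPM and Cxcl10 at 336 against 602 CPM. Among myeloid attractants, which went both ways (median -0.10 (-0.97 to 0.43)), Ccl2 measured 1325 against 3684 CPM and Ccl7 1078 against 3183 CPM. Genes of alternative activation had 2 higher and 2 lower of 10 (median -0.43 (-0.84 to 0.44)). Arginase (Arg1) measured 986 against 514 CPM and the chemokine Ccl8 2584 against 5805 CPM. The unnamed cluster of 142, 174 and 219 cells with macrophage-like genes had Ccl12, Ccl7 and Ccl8 among its top 10 genes. Its cells are not part of this class. Hypoxia genes had 2 of 9 higher (median 0.38 (0.26 to 0.65)), among them Ankrd37 (53.5 against 33.4 CPM), and complement genes 2 of 7 (median 0.49 (-0.05 to 0.94)), with Cfh at 58.5 against 27.4 CPM.

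Macrophage-like cells lay in 2 clusters whose mix differed: the cluster marked by Mrc1, Cd163 and Lyve1 held 354 of 1295 cells with vehicle, 344 of 950 with MCB-294 and 549 of 1310 with MCB-36. At the higher resolution 1 macrophage-like cluster held 611, 61 and 125 cells. The clusters were not compared apart. Lists in this class include the mix. With MCB-36 the alternative-activation list was higher for 5 of 10 members (median 0.55 (0.18 to 1.31)), with the haemoglobin scavenger receptor Cd163 at 87.6 against 34.8 CPM (ratio 2.52, 2.11 to 3.01), Retnla at 25.6 against 6.64 CPM and Arg1 at 890.5 against 514 CPM; at a 2-fold limit 3 were higher. Tns1 measured 62.0 against 22.4 CPM. Lowest against vehicle were the histones Hist1h1b (34.6 against 158 CPM) and Hist1h2ae (8.10 against 31.2 CPM) and the receptor Slamf9 (24.9 against 114 CPM). The MAPK output list had a median of 0.15 (-0.35 to 0.30), with Ccnd1 at 157 against 286 CPM, and against MCB-294 5 of its 8 members were higher (median 0.84 (0.49 to 1.02)). T cell attractants had 1 higher and 3 lower of 6 (median -0.49 (-1.0 to 0.38)), Ccl5 being the higher one (376 against 224 CPM), and myeloid attractants 4 of 10 lower (median -0.51 (-0.67 to 0.07)). MHC class II genes had none called (median 0.35 (-0.06 to 0.49) with MCB-36, 0.14 with MCB-294), and the checkpoint ligand Cd274 (PD-L1) measured 90.6 CPM with vehicle, 144 with MCB-294 and 169.9 with MCB-36. Hypoxia genes had a median of 0.28 (-0.03 to 0.69) and complement genes of 0.08 (-0.56 to 0.54). Inflammatory genes had medians of 0.09 (-0.55 to 0.70) and -0.12 (-0.52 to 0.39) with MCB-294 and MCB-36, lipid and scavenging genes 0.22 (-0.57 to 0.95) and 0.33 (-0.42 to 0.68), lysosome genes 0.18 and 0.20, interferon response genes 0.05 and -0.05, MHC class I genes 0.00 and 0.01, and glycolysis genes 0.10 and 0.14.

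In monocyte-like cells with MCB-294 the interferon response was lower for 6 of 20 genes (median -0.35 (-0.61 to -0.13)). Ifit3 measured 3.06 against 37.4 CPM, Isg15 136 against 349 CPM and Rsad2 39.1 against 136 CPM. MHC class II was lower for 4 of 7 (median -0.62 (-0.68 to -0.57)), with H2-Eb1 at 3055 against 4976 CPM. The cluster that forms this class had Mgl2, H2-Eb1, H2-Aa and H2-Ab1 among its top 10 genes beside the monocyte markers Chil3 and F10. A mix of cell types within it was not examined, so the values of this class include any change of mix. Myeloid attractants had 2 higher and 1 lower of 9 (median 0.44 (0.01 to 0.60)), Il6 measuring 91.2 against 31.9 CPM; with doublets kept the median was 0.06. Furthest above vehicle were Saa3 (492 against 33.3 CPM), the carbonyl reductase Cbr2 (117 against 6.93 CPM) and the leukotriene enzyme Ltc4s (41.4 against 1.39 CPM), and furthest below the lectin Mgl2 (31.4 against 331 CPM), Hist1h1b (5.36 against 84.5 CPM) and Pclaf (5.36 against 76.2 CPM), which acts in DNA replication. With MCB-36 the interferon median was -0.16 (-0.38 to 0.05), that of MHC class II 0.06 (-0.12 to 0.10) and that of myeloid attractants -0.04 (-0.36 to 0.25). Asgr2 measured 55.8 against 2.77 CPM, Saa3 275 against 33.3 CPM and the chaperone Hspa1a 104 against 29.1 CPM, and at the other end Hist1h1b 30.3 against 84.5 CPM, the oxysterol receptor Gpr183 32.8 against 88.7 CPM and Hist1h1e 40.2 against 103 CPM.

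NK-like cells had more RNA of the granzyme genes Gzmf (ENSMUSG00000015441, chromosome 14, 56205263 to 56211417, minus strand), Gzmg (ENSMUSG00000040284, chromosome 14, 56156582 to 56159579, minus strand) and Gzme (ENSMUSG00000022156, chromosome 14, 56117626 to 56120625, minus strand) with both compounds. Gzmf measured 60.7 CPM with vehicle, 3779 with MCB-294 and 2351 with MCB-36, Gzmg 180.5 CPM with vehicle, 3684 with MCB-294 and 2481 with MCB-36 and Gzme 143 CPM with vehicle, 1333 with MCB-294 and 926 with MCB-36. Few cells made this difference: at least 10 UMIs of these genes and Gzmd were seen in 7 of 284 NK-like cells with vehicle (2.46%, 0.997 to 5.01), 15 of 267 with MCB-294 (5.62%, 3.18 to 9.10) and 16 of 338 with MCB-36 (4.73%, 2.73 to 7.57). Any UMI of them was seen in 26, 31 and 30 cells (9.2%, 11.6% and 8.9%). Without the richest 10% of cells, which were 29, 27 and 34 cells, their summed level was 0, 10.8 and 0 CPM. The 0 with vehicle and with MCB-36 was certain, as fewer cells than that held any UMI. Since these neighbouring genes are near-identical the member is uncertain. The general cytotoxic list had a median of -0.14 (-0.31 to 0.27) with MCB-294 and -0.09 (-0.22 to 0.21) with MCB-36. Lowest against vehicle were Cxcl10 (20.5 against 148 CPM with MCB-294, 34.2 against 148 CPM with MCB-36), Top2a (42.5 against 194 CPM with MCB-294), Hist1h1b (132 against 469 CPM with MCB-294), Hspa1a (22.8 against 88.6 CPM with MCB-36) and Birc5 (66.1 against 223 CPM with MCB-36), a gene of mitosis. Interferon response genes had 4 of 11 lower with MCB-294 (median -0.45 (-0.74 to -0.06)) and 4 with MCB-36 (median -0.54 (-0.60 to -0.21)), with Isg15 at 118 CPM with vehicle, 22.0 with MCB-294 and 55.9 with MCB-36. In cells thinned to 2000 UMIs the medians over the members then measured were -0.03 and 0.21. The sign for MCB-36 was thus not kept, but fewer genes and cells were measured there, so the members can differ.

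T-like cells had less of Tox, a transcription factor of exhausted T cells (ENSMUSG00000041272, chromosome 4, 6686353 to 6991557, minus strand), at 158 CPM with vehicle, 26.6 with MCB-294 and 34.8 with MCB-36. Exhaustion genes were lower for 5 and higher for 1 of 7 members with MCB-294 (median -1.22 (-1.65 to -0.53)) and lower for 4 with MCB-36 (median -0.77 (-1.44 to 0.36)). T-like values include the mix of 2 clusters, which were not compared apart. The deeper one, with Pdcd1, Xcl1 and Ccl1 among its top 10 genes, held 71 of the T-like cells with vehicle, 15 with MCB-294 and 40 with MCB-36. The other held 183, 199 and 331. Ctla4 was higher with both compounds. The inhibitory receptors Pdcd1 (PD-1) and Havcr2 (TIM-3) measured 79.8 against 195 CPM and 36.3 against 85.9 CPM with MCB-294 and 114 against 195 CPM and 49.7 against 85.9 CPM with MCB-36, and Ctla4, the higher member, 707 against 354 CPM and 617 against 354 CPM. With doublets kept the MCB-294 median was -0.58 and Havcr2 had a ratio of 1.22, so that its direction was not kept. The RNA quality list, nuclear-retained RNAs, had medians in T-like cells of 0.55 (-0.74 to 0.67) with MCB-294 and 0.25 (-0.43 to 0.48) with MCB-36, and in NK-like cells of 0.53 (0.24 to 1.0) and -0.08 (-0.32 to 0.07). Malat1 in T-like cells measured 1.59 and 1.40 times vehicle. Genes of naive and memory T cells were higher for 4 of 6 with MCB-294 (median 1.04 (0.03 to 1.88)) and 4 with MCB-36 (median 0.78 (-0.01 to 1.48)), with the interleukin-7 receptor Il7r at 157 CPM with vehicle, 484 with MCB-294 and 416 with MCB-36. Highest against vehicle with MCB-294 were Tsc22d3 (397 against 85.9 CPM), the quiescence factor Klf2 (1430 against 323 CPM) and Txnip (252 against 75.8 CPM), and lowest Ccna2 (16.9 against 109.5 CPM), Tox and Stmn1 (43.6 against 192 CPM). With MCB-36 the chemokines Xcl1 (769.8 against 180.2 CPM) and Ccl1 (533 against 149.9 CPM) and Klhl6 (91.9 against 21.9 CPM) were highest and the receptor Klre1 (21.1 against 116 CPM), Tox and Hist1h1b (232 against 687 CPM) lowest; Xcl1 and Ccl1 had ratios of 0.536 and 0.691 with doublets kept. Regulatory T genes had medians of 0.37 (-0.48 to 0.79) and 0.26 (-0.05 to 0.36) with MCB-294 and MCB-36, cytotoxic genes 0.24 (-0.80 to 0.89) and 0.01 (-0.20 to 0.37), and activation genes 0.25 (-0.48 to 0.54) and 0.30 (-0.23 to 0.93).

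Fibroblast-like cells parted between the compounds in their matrix genes. With MCB-294 4 of 10 were lower (median -0.42 (-0.70 to -0.07)), with MCB-36 none was called (median 0.35 (0.27 to 0.49)), and MCB-36 lay above MCB-294 for 6 of them (median 0.77 (0.55 to 0.99)). Malat1, of the RNA quality list, parted the other way, with ratios to vehicle of 1.67 and 0.847. The collagen crosslinker Lox measured 419.6 CPM with vehicle, 242 with MCB-294 and 504 with MCB-36, fibronectin (Fn1) 3444 CPM with vehicle, 2058 with MCB-294 and 4076 with MCB-36 and Col6a1 665 CPM with vehicle, 408 with MCB-294 and 825 with MCB-36. Contractile myofibroblast genes had 3 of 6 lower with MCB-294 (median -0.92 (-2.20 to 0.14)) and 4 with MCB-36 (median -0.77 (-1.73 to 0.17)). Smooth muscle actin (Acta2) measured 179 CPM with vehicle, 31.5 with MCB-294 and 70.4 with MCB-36. Tagln measured 102 CPM with vehicle, 25.9 with MCB-294 and 22.8 with MCB-36. In cells thinned to 2000 UMIs the medians over the members then measured were -0.34 and -0.36. Myeloid attractants had 4 of 12 lower with MCB-294 (median -0.04 (-1.32 to 0.20)) and 6 with MCB-36 (median -0.62 (-0.92 to -0.26)), Cxcl5 measuring 295 CPM with vehicle, 55.2 with MCB-294 and 95.2 with MCB-36. Inflammatory fibroblast genes had medians of 0.18 (-0.81 to 0.34) and -0.31 (-1.33 to 0.35). Tumour RNA in these 132, 96 and 137 cells was estimated at 45.2%, 43.0% and 35.4% of its level in tumour-like cells. By this estimate it accounted, in the median over list members, for at most 1.71% of the level of matrix genes. For G2/M genes it was at least 86.7%. The estimate can include the cells' own expression, since its genes were those lowest in the class itself and included Ran, H2afz and Pclaf. It also does not cover the unequal dilution of all other genes, matrix genes included, by unequal amounts of tumour RNA. The cell cycle and MAPK lists are therefore not read in this class. With each library clustered on its own the matrix median with MCB-294 was -0.11.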

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

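The 10 tests of the 3 patterns, the setting of tumour-like cells without a G2/M UMI and the values with tumour RNA taken off were chosen only after the result was seen. The first 7 results are lists whose median lay on one side of vehicle in a host class and on the other side in tumour-like cells under the same comparison. The difference between the classes was not tested in any of them.

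With MCB-294 the hypoxia list lay at 0.38 in macrophage-like and -0.39 in tumour-like cells, a gap of 0.77 on the log2 scale. The immediate early list lay at 0.23 in NK-like and -0.95 in tumour-like cells with MCB-294, a gap of 1.18, although 5 of its 12 NK members are over 10 times higher in another class. With MCB-36 it lay at 0.20 in fibroblast-like and -0.18 in tumour-like cells, a gap of 0.38; the fibroblast-like median was 0.51 with tumour RNA taken off. Interferon response genes with MCB-294 lay at -0.35 in monocyte-like against 0.44 in tumour-like cells, a gap of -0.79. In NK-like cells they lay at -0.45, a gap of -0.89, but at -0.03 over the members measured after thinning to 2000 UMIs. With MCB-36 they lay at -0.54 in NK-like against 0.17 in tumour-like cells, a gap of -0.71, but neither side kept its sign. The NK-like median was 0.21 over the members measured in cells thinned to 2000 UMIs. The tumour-like one was -0.02 in thinned cells without a G2/M UMI. Myeloid attractants with MCB-294 lay at 0.44 in monocyte-like against -0.81 in tumour-like cells, a gap of 1.25, with the monocyte-like median at 0.06 when doublets were kept.

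The first pattern weighed is that MAPK output genes were lower in tumour-like cells with MCB-294 than with MCB-36. Fewer dividing cells were examined as a source in tumour-like cells without a G2/M UMI after thinning to 2000 UMIs. There the median of MCB-36 against MCB-294 was 0.67, against 0.72 (0.47 to 1.25) in all. Cells rich in G2/M RNA therefore do not account for the whole difference. Cells that lost their G2/M UMIs by thinning and cells in DNA replication were not removed, so a part played by division stays open. A handling difference that induces immediate early genes in all cells is argued against by a median of -0.04 over the 5 host classes, against 0.74 in tumour-like cells. The lowest of the 5 class medians was -0.45 and the highest 0.05. A mixture of cells as with vehicle and cells as with MCB-294 predicts 18.9% of tumour-like cells without a MAPK output UMI in the MCB-36 library. There 13.8% (13 to 14.7) was seen, and an even reduction in all cells predicts 12.9%. Both predictions lie outside that interval, the mixture's further from the value seen, and other mixtures were not examined. Dose, compound and a peculiarity of 1 library stay open, MAPK output being also higher with MCB-36 in macrophage-like cells (0.84), and replicate libraries at matched doses would be needed to separate them.

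The second pattern is that 5 glucocorticoid-induced genes, picked after their values were seen, had median ratios to vehicle above 1 with both compounds in tumour-like and host cells, although with MCB-36 only 2 of the 5 were at least 1.5-fold higher in tumour-like and in fibroblast-like cells. RNA of tumour-like cells does not account for it in macrophage-, NK- and T-like cells, where the lowest median ratio to vehicle of 5 such genes was 2.04 with that RNA taken off. Harvest at another hour of the day could shift both these genes and the clock genes, and it stays open: Dbp was lower in tumour-like cells with both compounds (0.408 and 0.220), while Arntl, whose rhythm runs opposite, had ratios of 0.949 with MCB-294 and 1.40 with MCB-36. A hormone response of the treated mice, such as to stress, stays open as well, since hour, treatment and library cannot be told apart here.

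The third pattern is that cell cycle genes were lower in host classes with both compounds. RNA of tumour-like cells is argued against as the whole source in macrophage-, NK- and T-like cells, where the G2/M median nearest 0 was -0.99 with that RNA taken off, and so are doublets with tumour-like cells, with -1.39 as the value nearest 0 in the 50% of cells holding the least tumour RNA. In monocyte-like cells losing all tumour RNA in the vehicle library would give a G2/M median of -0.76. That argues against such a loss as the whole source for MCB-294, at -2.59 (-3.07 to -1.93). It cannot be told apart from the result for MCB-36, at -0.52 (-0.88 to -0.28). In fibroblast-like cells tumour RNA may be the source, estimated at 86.7% or more of the level of the median G2/M gene. That estimate can include the cells' own expression. The T-like value for MCB-36 also depends on the doublet setting, since it was -0.02 when doublets were kept, which left 1 cluster unnamed. The mix of macrophage-like clusters stays open as well, so a lower division of macrophage- and NK-like cells remains a hypothesis, found and tested on the same libraries.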

How the results depend on the processing

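The unthinned shares, the cells without a G2/M UMI, the counts without Gm42418 and AY036118, the lists without members far higher in another class and the tumour RNA step were chosen only after the results were seen. No paired analysis was possible because each group has 1 library, and no library could be left out. The MAPK output median in tumour-like cells kept its direction under every alternative run, from -1.42 to -0.96 with MCB-294, from -0.41 to -0.19 with MCB-36 and from 0.67 to 1.01 between them. So did G2/M with MCB-294, from -1.03 to -0.83. Out of all kept cells, the NK-like ratio to vehicle ranged from 0.997 to 1.02 with MCB-294 and from 1.24 to 1.28 with MCB-36. The smaller tumour-like share with MCB-36 enters that NK-like ratio. Out of T- and NK-like cells, the regulatory T-like ratio ranged from 0.623 to 0.852 and from 0.907 to 1.29. Changes of sign were counted only for lists, genes and shares called in the main analysis. For a gene or share that meant a ratio of at least 1.5-fold with an interval excluding 1. Of 3540 list medians under alternatives 3394 stayed within the main interval, 141 lay outside it and 5 changed sign. Of 4570 values for single genes 3588 stayed within it, 7 changed sign and the others lay outside it. Of 322 for shares 276 stayed within it and 46 lay outside it. Member counts were judged by another measure and depended on the limit for calling: with 2-fold in place of 1.5-fold, 155 of 209 fell by more than 1.5-fold. In tumour-like cells with MCB-294 the median log2 ratio of all genes was -0.065 in CPM and 0.036 in CPM without mitochondrial and ribosomal protein genes. The genes named by size were also named with a constant of 1 CPM for 17 and 18 of 20 in tumour-like cells, 5 and 6 of 6 in macrophage- and T-like, and 6 and 5 of 6 in monocyte- and NK-like cells.

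For the values that moved, the cause was not tested except where stated. With a mean over cells of each cell's CPM the tumour-like G2/M median with MCB-36 was -0.47, and Gzmf in NK-like cells had a ratio of MCB-36 to MCB-294 of 1.13. With each library clustered on its own, that G2/M median was -0.33, the exhaustion median in T-like cells with MCB-294 -1.77, the tumour-like ratio with MCB-36 0.805, the macrophage- and monocyte-like ratio 1.22 with MCB-294 and 1.44 with MCB-36, the CD8 T-like ratio with MCB-36 0.223 and the Ccl5 ratio in macrophage-like cells with MCB-294 1.46; no CD8 T-like cluster was named with MCB-294 there, nor in any library with doublets kept. The exhaustion median with MCB-36, whose interval includes 0 and which is therefore counted as kept, ranged from -0.82 to 0.03, the latter with doublets kept. In thinned tumour-like cells without a G2/M UMI the interferon median was -0.23 between the compounds and -0.02 with MCB-36 against vehicle. At a 2-fold limit, which by construction calls fewer genes, the counts were 9 for lower G2/M genes with MCB-294, 0 for higher ones between the compounds, 4 for higher MAPK output genes between the compounds, 0 for lower ones with MCB-36, 2 for lower exhaustion genes with MCB-36, 1 for higher interferon genes with MCB-294, 0 for lower ones between the compounds and 3 for higher alternative-activation genes with MCB-36. With doublets kept, which left the deeper CD8 T-like cluster unnamed, the T-like ratio to vehicle was 1.17 with MCB-294 and 1.94 with MCB-36, Xcl1 and Ccl1 with MCB-36 had ratios of 0.536 and 0.691, Ccl1 between the compounds 0.905 and Havcr2 with MCB-294 1.22. The same setting gave a glycolysis median of -0.01 in monocyte-like cells with MCB-36 and a Mki67 share ratio of 0.608 with MCB-36. At resolution 0.5 and 2 the CD8 T-like ratio was 0.224 and 1.55 with MCB-294 and 0.240 and 1.68 with MCB-36. After thinning to 2000 UMIs, over the members then measured, the interferon median in NK-like cells with MCB-36 was 0.21. The immediate early median in NK-like cells between the compounds was then 0.14, and the Klhl6 ratio in T-like cells with MCB-294 was 0.708. With tumour RNA taken off, the G1/S median in fibroblast-like cells with MCB-294 was 0.52. At 5000 UMIs the Mki67 share ratio was 0.497 with MCB-294 and 0.589 with MCB-36, at 1000 UMIs 0.582 with MCB-36, and unthinned the Top2a share ratio was 0.830 with MCB-36.

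Depth limits the T- and NK-like classes: at a median of 1523 to 1894 UMIs per cell, thinning to 2000 UMIs kept 61 to 122 T-like and 106 to 160 NK-like cells per library.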

Other observations

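The tests on the hour of harvest and the genes of the first paragraph were chosen only after the results were seen. Genes that glucocorticoid hormones induce had median ratios to vehicle above 1 with both compounds in every class compared, although with MCB-36 only 2 of the 5 genes were at least 1.5-fold higher in tumour-like and in fibroblast-like cells. Over Tsc22d3, Fkbp5, Sgk1, Klf9 and Per1, the median ratio to vehicle with MCB-294 was 1.68 in tumour-like, 2.73 in macrophage-like, 3.36 in monocyte-like, 2.24 in NK-like, 4.02 in T-like and 2.07 in fibroblast-like cells. With MCB-36 it was 1.499, 1.91, 1.61, 1.89, 2.75 and 1.32 in the same order. These 5 were picked after the values were seen from a longer set, in which other induced genes did not rise everywhere. Cebpd in macrophage-like cells had ratios of 0.859 (0.739 to 0.997) and 0.745 (0.644 to 0.861), Glul in NK-like cells 0.913 and 0.960, and Mt1 in T-like cells with MCB-36 0.995. The medians over the 5 genes carry no interval and can rest on few counts. Klf9 gave the NK-like median with MCB-36 (19 counts against 7 with vehicle) and the T-like one with MCB-294 (14 against 5). Fkbp5, a chaperone partner of the hormone receptor, had ratios with MCB-294 of 2.85 in tumour-like, 3.25 in macrophage-like and 4.83 in T-like cells, and with MCB-36 of 1.499, 2.37 and 2.75. Tsc22d3 had ratios of 2.70, 2.30 and 4.62 with MCB-294 and of 2.09, 2.22 and 3.02 with MCB-36. The metallothioneins, higher than with vehicle under MCB-36, measured 2092 CPM (Mt2) and 3059 CPM (Mt1) in tumour-like cells with MCB-294.

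Clock genes differed too. In tumour-like cells Dbp had a ratio to vehicle of 0.408 with MCB-294 and 0.220 with MCB-36, Nr1d1 of 0.753 and 0.514, and Arntl of 0.949 (0.874 to 1.03) and 1.40 (1.31 to 1.51). Dbp was also lower in macrophage-like cells (0.154 and 0.278), and in fibroblast-like cells it had ratios of 1.15 and 0.362.

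Some values belong to no comparison. Gm42418, a locus that overlaps ribosomal RNA, measured 5196 CPM with vehicle, 10230 with MCB-294 and 8605 with MCB-36 in tumour-like cells, and 32302, 45642 and 70432 CPM in macrophage-like cells. The Y-linked Ddx3y measured 0.109, 0.0658 and 0.0847 CPM in tumour-like and 41.5, 52.8 and 62.9 CPM in macrophage-like cells. The NK receptor gene Klra8 had 0 counts in NK-like cells of all 3 libraries, which allows up to 6.05, 5.81 and 4.21 CPM at the upper 95% Poisson bound, and Klra4 had 1, 2 and 10 counts. C57BL/6 mice carry both genes and BALB/c mice lack them, so the values put the C57BL/6 label in doubt, and no test of the strain was made. Klra3 measured 277 CPM with vehicle, 211 with MCB-294 and 216 with MCB-36.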
